A study of Drosophila melanogaster with 2 samples.

How the data were processed

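Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos of a transgenic line that stably expresses MTF-1 with GFP at its C terminus, per the labels. Embryos were 0 to 24 h old and both sexes were pooled. The series holds 1 group of 2 samples, the biological replicates numbered 2 and 4 in the labels, each with its own biosample entry from the same fly line. The labels do not say that the embryos came from separate crosses. Chromatin was sonicated to fragments of 200 to 800 bp, per the labels. The titles, the assay label and the antibody label (MTF-1) describe libraries of an immunoprecipitated transcription factor, while the free-text description of both samples calls them input controls. The samples were treated as immunoprecipitates, because the deposited read-me names a separate, shared file among the sources of each peak list. That shared file was taken to be the control and was not analysed here.

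Peak lists on the dm6 assembly were used. Per the deposited read-me, a list of peaks and background was made for each replicate and another on the pooled alignments of both replicates. The thresholded list was derived from those 3 lists by the irreproducible discovery rate (IDR), a procedure meant to keep peaks ranked alike in replicates. The thresholded list still holds peaks that rank low in, or are absent from, 1 replicate's list. The peak at Tsf2, of rank 2166, ranked 11414 in replicate 2, and that at Sod2, of rank 3508, had no region there. The aligner, the peak caller, the IDR threshold and the numbers of reads are not given in the sources used here. The replicate lists and the pooled list hold 30000 regions each, and the thresholded list holds 3587. The signal value of each region is the deposited value from the authors' peak caller; its scale is not stated, so levels of signal were not compared between lists. Signal was used to describe, rank and filter regions within 1 list, to compare groups of peaks of 1 list, and to correlate the replicates over shared regions. The authors' lists also give −log10 of a q-value for each region, which lay between 0.162 and 3.80 over all 4 lists. Signal in the thresholded list is that of the pooled list and has no SD. The depth of each sample is unknown, so no interval given here covers the sampling of reads; the 95% intervals (exact Clopper-Pearson for shares, bootstrap for differences between summit and flank) cover the counting of regions or genes only. P-values over regions or genes are not p-values over biological replicates, and neighbouring regions and genes are not independent.

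Gene models came from Ensembl release 115 on BDGP6.54, which is the same assembly as dm6. In the genome sequence used, 0 regions of any list lay beyond a chromosome end, a check that does not involve the gene models. Coordinates are 1-based. The analysis used chromosomes 2L, 2R, 3L, 3R, 4 and X, 13945 protein-coding genes and 23998 distinct transcript starts of all biotypes. A gene had a peak when a summit lay within 1000 bp of any of its transcript start sites (TSSs), so 1 peak could count for several genes. Each summit was placed in 1 annotation class, in the order promoter (within 500 bp of a TSS), 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic. The background comprised 14859 regions of the pooled list with a signal below that list's median, none of which overlapped a thresholded peak. Shares of peaks were compared with it by two-sided Fisher's exact tests, with Benjamini-Hochberg (BH) adjustment over the annotation classes.

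Sequence motifs were searched on both strands within 50 bp of each summit, a window of 101 bp. The same peak's window centred 500 bp to 1 side served as its flank, with the sides drawn at random once for each set of peaks, so that 1 peak can have different flanks in different sets, and the pair was compared with a two-sided exact McNemar test. The metal response element (MRE), the binding site of MTF-1, was searched as its core TGCRCNC (R is A or G, N any base). A list of 17 other motifs was BH-adjusted over the list, and all 2080 6-mers, each joined with its reverse complement, were BH-adjusted over the 6-mers. The 8 forms of the core were compared in the same way, BH-adjusted over the 8 forms, a comparison chosen after the data were seen. The signal of peaks with and without a core was compared by a two-sided permutation test of the difference of medians on the log2 scale with 100000 resamples.

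The shares of 13 documented MTF-1 target genes and of 20 gene lists with a peak were compared with all other protein-coding genes by two-sided Fisher's exact tests, BH-adjusted over the 20 lists (an exact adjusted p is the BH-adjusted p of an exact test), and with 10000 random lists matched on the number of TSSs. All written list members were found in the annotation, 6 of them under a newer symbol. For replicate overlap, the 3587 regions of highest signal of each replicate were compared at a minimum overlap of 1 bp, with 10000 random draws of as many regions from each list as chance. Correlations of log2 signal used regions overlapping in both replicate lists and 100000 permutations. The neighbourhood of the MTF-1 gene, 20 kb on each side, was compared with 10000 windows of the same size around other protein-coding genes.

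The planned tests, windows, distances, motifs, gene lists and the naming rule were fixed before the data were examined. The split of peaks by rank and the tests named as chosen or devised after the data were seen were not. The rule named the documented targets, the genes nearest to the 15 peaks of highest signal, up to 4 members of each list with a BH-adjusted p under 0.05 (all members with a peak for metal lists), the 5 strongest peaks with an MRE core and the 5 6-mers of smallest adjusted p. The gene nearest to a summit was named together with the nearest gene on the other strand where that lay within 1 kb. A stricter set (the 1793 thresholded peaks of higher signal), each replicate's 3587 strongest regions alone, other windows, distances, backgrounds and overlap rules, 7-mers and random matched lists were the alternatives. The naming rule also took an item that is not reported here. Alternatives chosen after the data were seen drew the sides of the flanks 1000 other times, counted a peak only for the gene with the TSS nearest to its summit, or left out the 55 protein-coding genes within 100 kb of the MTF-1 gene.

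Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9. The statistics were tested on simulated data. Of 20 6-mers planted in 2% of windows, 12 were recovered among 2080 with 0 false calls; with planting in 5%, 20 were recovered with 44 other calls, which include 6-mers overlapping the planted ones. A core added to 3% of windows was called in 190 of 200 trials, and 12 of 200 trials with none added were called. For gene lists, 234 of 250 lists hit about 3 times as often were called, with 8 false calls.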

Results

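MTF-1, metal regulatory transcription factor 1, is a zinc-finger protein that binds metal response elements (MREs) and controls genes for storing and moving metals. Its binding sites were mapped by ChIP-seq in 0 to 24 h Drosophila embryos of both sexes that carried GFP-tagged MTF-1, in 2 biological replicates (numbers 2 and 4) of 1 group. The thresholded list held 3587 peaks with a median width of 344 bp (range 86 to 885). Signal values in it are the authors' own, given per peak from the pooled reads, and ran from 104.02 to 16205 with a median of 154. Peaks had been called in each replicate and on the pooled reads. Read depth is unknown, the labels name no group without the tag, and the shares describe where regions lie, not how binding changed with metal.

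The question addressed first was which genes MTF-1-GFP occupied most strongly. MtnA, which encodes a metal-sequestering metallothionein, had the strongest peak of the list, with a signal of 16205, 106 times the median. The ferritin genes Fer1HCH and Fer2LCH, which encode the iron storage shell and are transcribed divergently, shared the peak of rank 2, at 11844 or 77.1 times the median. These 2 peaks ranked first and second in each replicate, and both stood apart from the rest, since the peak of rank 3 had a signal of 1967. Ctr1B, which encodes a copper importer, had the peak of rank 5 (1874), which ranked 3 in replicate 2 and 6 in replicate 4. In all, 10 of the 13 documented target genes had a peak (76.9%; 95% exact interval 46.2 to 94.96), against 16.9% of all other protein-coding genes (two-sided Fisher's exact p = 3.40e-06). Random lists matched on TSS number averaged 3.09 genes with a peak (one-sided permutation p = 0.0001, the smallest possible with 10000 lists). Each replicate's 3587 strongest regions also reached 10 of the targets.

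The MtnA peak covered 3R 9784095 to 9784823, a region that holds the TSSs of both MtnA and CG8500. Its summit lay between them, 143 bp from the MtnA TSS and 140 bp from that of the divergent gene CG8500, so the list alone does not assign it to either. The MRE core TGCACAC occurred 24 bp and 60 bp from that summit, at 3R 9784486 to 9784492 and 9784450 to 9784456. The window at 3R 9784463 to 9784563 reads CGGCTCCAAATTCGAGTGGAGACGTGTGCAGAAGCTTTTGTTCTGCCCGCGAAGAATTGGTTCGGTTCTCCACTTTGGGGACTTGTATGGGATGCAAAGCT on the plus strand. The ferritin peak covered 3R 30386641 to 30387525 inside Fer1HCH, with its summit in an annotated 5′ UTR, 586 bp from a Fer1HCH TSS and 790 bp from a Fer2LCH TSS. It held 4 cores within 100 bp of the summit, 3 of them TGCACAC and 1 TGCGCAC. The sequence at 3R 30386964 to 30387064 is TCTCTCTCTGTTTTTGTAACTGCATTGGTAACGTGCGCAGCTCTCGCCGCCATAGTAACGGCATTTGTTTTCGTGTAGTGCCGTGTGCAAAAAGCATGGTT. Further peaks at the ferritin pair ranked 36, 123, 148 and 1622, the last 2 being summits in 1 region, and a weaker one (signal 109) lay inside Fer1HCH at 3R 30385630 to 30385973. The Ctr1B peak, 3R 8316739 to 8317152, lay 684 bp from the Ctr1B TSS, but the TSS of lncRNA:CR45215 (56 bp) and that of Coq2 (385 bp), a coenzyme Q synthesis gene, were nearer. Its 3 cores fell within 50 bp of the summit, in the window at 3R 8316878 to 8316978, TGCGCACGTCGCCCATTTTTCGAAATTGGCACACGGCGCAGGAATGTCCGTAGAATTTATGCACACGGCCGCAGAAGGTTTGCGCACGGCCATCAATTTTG.

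**Figure D1:**
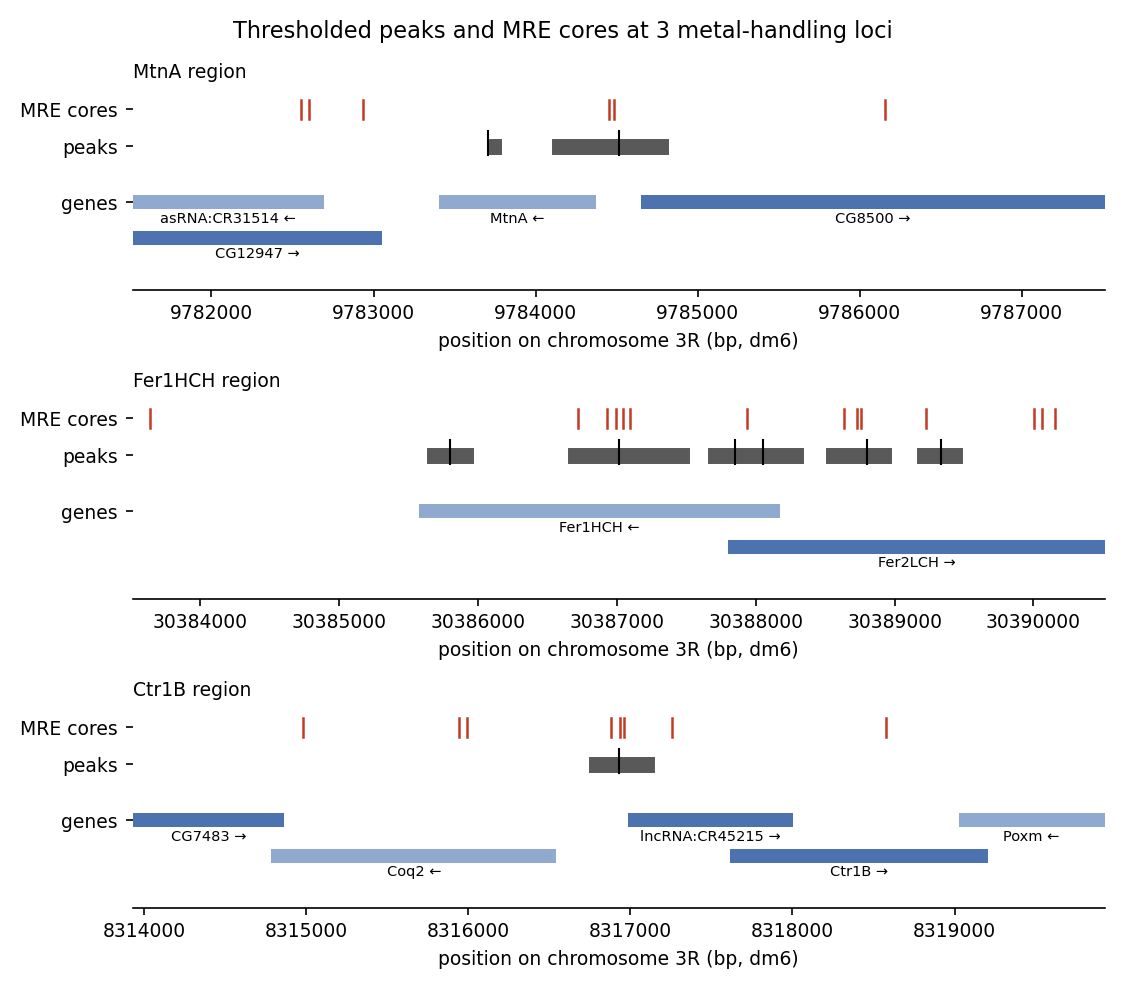
Thresholded peaks (grey boxes, summits as black lines), MRE cores (red ticks) and genes (blue, arrows giving the strand) by position on chromosome 3R in bp at the MtnA, ferritin and Ctr1B loci. The MtnA summit lies between 2 divergent TSSs and the strongest ferritin summit lies inside Fer1HCH among 4 cores.

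Weaker peaks marked the other documented targets. MtnD and MtnE, neighbouring metallothionein genes, shared the peak of rank 98 (signal 623) at 3R 20534661 to 20534952, with 4 cores within 100 bp. MtnC had the peak of rank 1139 (signal 195) with its summit 85 bp from the TSS and 3 cores within 50 bp. ZnT63C, a zinc exporter gene, had an intronic peak of rank 41 (signal 906) with a TGCGCAC core 23 bp from the summit. ZnT35C, another zinc transporter gene, had a peak of rank 278 nearer to the TSS of dao (546 bp) than to its own (619 bp), and a weaker one of rank 1224 at 98 bp with 1 core. The MTF-1 gene had a peak of rank 1318 (signal 179) with its summit 48 bp from the TSS and no core within 100 bp. MtnB, MtnF and CG10505, which encodes an ABC transporter, had no thresholded peak. MtnB carried 4 cores within 300 bp of a TSS, yet its best candidate region ranked 11186 of 30000 in the pooled list, and that of CG10505 ranked 5873. MtnF had no candidate region within 1 kb. Where a peak counted only for the gene with the nearest TSS, 8 of the 13 targets had one (Fisher's exact p = 4.27e-05), without Ctr1B and MtnD. The strongest peak of the list then counted for CG8500, and MtnA had only a peak of rank 1828 (signal 151), as ZnT35C had only that of rank 1224.

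**Figure D2:**
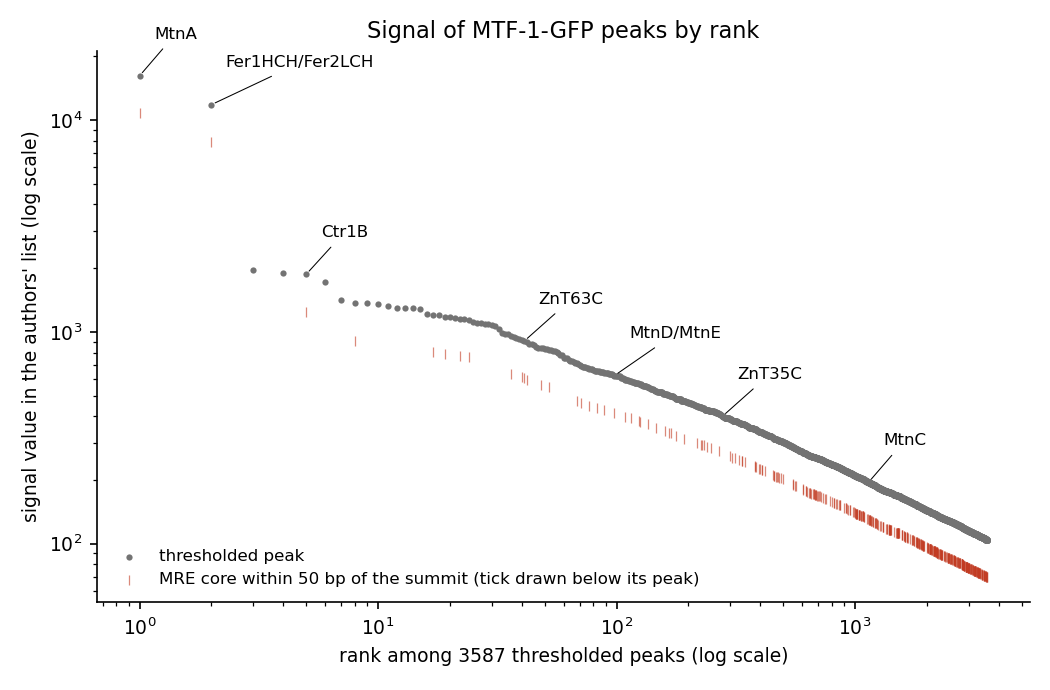
The authors' signal value (log scale) of each of the 3587 thresholded peaks against its rank (log scale), with the best peak of documented targets other than MTF-1 labelled and a red tick under each peak that has an MRE core within 50 bp of the summit. The MtnA and ferritin peaks, at 16205 and 11844, lie apart from that of rank 3 at 1967.

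Among the 15 strongest peaks, 10 lay in promoters, 3 in introns and 13 within 1 kb of a TSS, and 4 had a core within 50 bp of the summit. Behind MtnA, ferritin and Ctr1B, the fourth with a core was the peak of rank 8 at the promoter of Ggt-1 (X 18512198 to 18512648, signal 1367), whose product belongs to the gamma-glutamyl transpeptidases that break down glutathione. The fifth strongest peak with a core ranked 17 (3L 2089837 to 2090293, signal 1207) and lay in a 3′ UTR of sls, which encodes a titin-like muscle protein. The other peaks among the 15 lacked a core in that window. They lay at the promoters of Ugalt (rank 3, signal 1967), a UDP-galactose transporter gene with eIF2Bbeta on the other strand, lncRNA:CR31840 (rank 4, 1892), CG14100 (rank 6, 1713), px (rank 7, 1413), CG1888 (rank 12, 1294), Alg3 with asRNA:CR45326 (rank 14, 1291) and the divergent Art3 and mRpS10 (rank 15, 1287). Introns of ph-p (rank 10), a Polycomb group gene, of sbb (rank 11, 20104 bp from its nearest TSS) and of CG11050 (rank 13) held 3 of them, and the peak of rank 9 lay 761 bp from the TSS of jp.

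Next, gene groups were compared. Of all 13945 protein-coding genes, 2368 (17.0%) had a peak within 1 kb. Cytosolic ribosomal protein genes stood highest, with 70 of 90 (77.8%; 95% interval 67.8 to 85.9) against 16.6% of other genes (Fisher's exact, BH-adjusted p = 1.53e-35). Their strongest peaks lay on the TSSs of RpS27 (rank 23, signal 1145, 15 bp), RpS4 (rank 61, 2 bp), RpL14 (rank 64, 9 bp) and RpL7 (rank 68, 36 bp). Within 300 bp of a TSS, RpL7 had 3 MRE cores, while RpS27, RpS4 and RpL14 had none. In each replicate alone, 69 and 70 of these genes had a region within 1 kb. Before thresholding, 94.4% of them already had a candidate region within 1 kb, against 55.5% of other genes. Metallothionein genes had a peak in 4 of 6 (MtnA, MtnC, MtnD and MtnE; exact adjusted p = 0.0233), a call that ended when peaks counted only for the nearest TSS (3 of 6, adjusted p = 0.0620) or for genes within 5000 bp (adjusted p = 0.182). The other metal lists did not pass. Zinc transporter genes had a peak in 5 of 17 (Zip99C at rank 18, ZnT63C, ZnT35C, ZnT77C at 1482 and foi at 1962; exact adjusted p = 0.317), although replicate 2 alone reached 7 of 17 (adjusted p = 0.0383). Copper genes had a peak in 2 of 8 (Ctr1B and the copper pump gene ATP7 at rank 297; exact adjusted p = 0.742). Iron genes had a peak in 5 of 13 (both ferritin genes, Tsf2 at 2166, mfrn at 2738 and Fer3HCH at 3432; exact adjusted p = 0.0996), replicate 2 alone reached 3 of 13 (adjusted p = 0.574), and the 9 of 13 within 5000 bp gave an adjusted p of 0.0397.

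Stress and cell cycle lists passed, but their calls were lost under other settings, all 3 of them in the stricter set of 1793 peaks (exact adjusted p from 0.190 to 0.777). Heat shock genes had a peak in 8 of 18 (exact adjusted p = 0.0199), led by Hsp83 (rank 22, signal 1152), which encodes the fly Hsp90, Hsp27 (rank 211), stv (rank 1610) and Hsp26 (rank 1722). However, 6 genes of the list, among them Hsp27, Hsp26 and Hsp22 with a peak, form a cluster within 100 kb of the MTF-1 gene. Without the genes near MTF-1, 5 of 12 heat shock genes had a peak, a share of 41.7% in place of 44.4%, and with fewer genes the exact adjusted p was 0.0764. In that neighbourhood 22 of 55 protein-coding genes had a peak. Glutathione and redox genes had a peak in 7 of 15 (exact adjusted p = 0.0209), including Keap1 (rank 648), GstD1 (1369), cnc (1810) and Prx2 (2428), but not beyond lists matched on TSS number (adjusted p = 0.216) nor in either replicate alone (adjusted p = 0.169 and 0.0623), within 500 bp (0.103) or within 5000 bp (0.1001). DNA replication and cell cycle genes had a peak in 7 of 16 (exact adjusted p = 0.0247), among them dup (rank 1339), CycB (1566), stg (1815) and Mcm2 (2440), and this call was lost against matched lists (adjusted p = 0.0790) and in replicate 2 alone (adjusted p = 0.298).

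Several lists had fewer peaks than other genes. The chemoreceptor list, which also holds odorant-binding protein (Obp) genes, had a peak in 3 of 230 genes (exact adjusted p = 5.62e-14). These were Obp99b (rank 244), Or88a (1521) and Gr64a (2708). Cuticle protein genes had one in 2 of 70 (Cpr73D at 1761 and Cpr65Av at 2336, exact adjusted p = 0.00293). Candidate regions within 1 kb were scarcer too, at 23.5% of the chemoreceptor list against 56.3% of other genes. For cuticle protein genes the shares were 38.6% against 55.9%. Part of the shortfall was therefore present before thresholding. None of the 32 proteasome genes had a peak within 1 kb (exact adjusted p = 0.0156), but the call was lost in each replicate alone (1 of 32 in both, adjusted p = 0.114 and 0.0657), in the stricter set (0 of 32, 0.179) and by nearest TSS (0 of 32, 0.0620), where fewer of the other genes had a peak (9.56% and 12.5%), and 14 had a peak within 5000 bp (adjusted p = 0.432). None of the 111 replication-dependent histone genes had a peak (exact adjusted p = 1.28e-08), and none had even a candidate region within 1 kb, while 56.2% of other genes had one, so binding at these repeated genes could not be assessed. Translation factor genes (15 of 52, exact adjusted p = 0.0779) and mitochondrial ribosomal protein genes (15 of 73, adjusted p = 0.578) did not pass; translation factors did in replicate 4 alone (17 of 52, adjusted p = 0.0178), within 500 bp (14 of 52, adjusted p = 0.0386) and in the stricter set (11 of 52, adjusted p = 0.0475), and mitochondrial ribosomal protein genes within 5000 bp (35 of 73, adjusted p = 0.0397). By nearest TSS only, mitochondrial ribosomal protein genes had fewer peaks than other genes (3 of 73, 4.11% against 12.6%) without passing (exact adjusted p = 0.0620). Developmental lists did not pass either: segmentation 3 of 19, Hox 0 of 8, dorsoventral patterning 2 of 11, neural 1 of 16, muscle 4 of 13 and gut, fat body and blood 1 of 13 (exact adjusted p from 0.392 to 1), with muscle at 6 of 13 in replicate 2 alone (adjusted p = 0.0383).

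**Figure D3:**
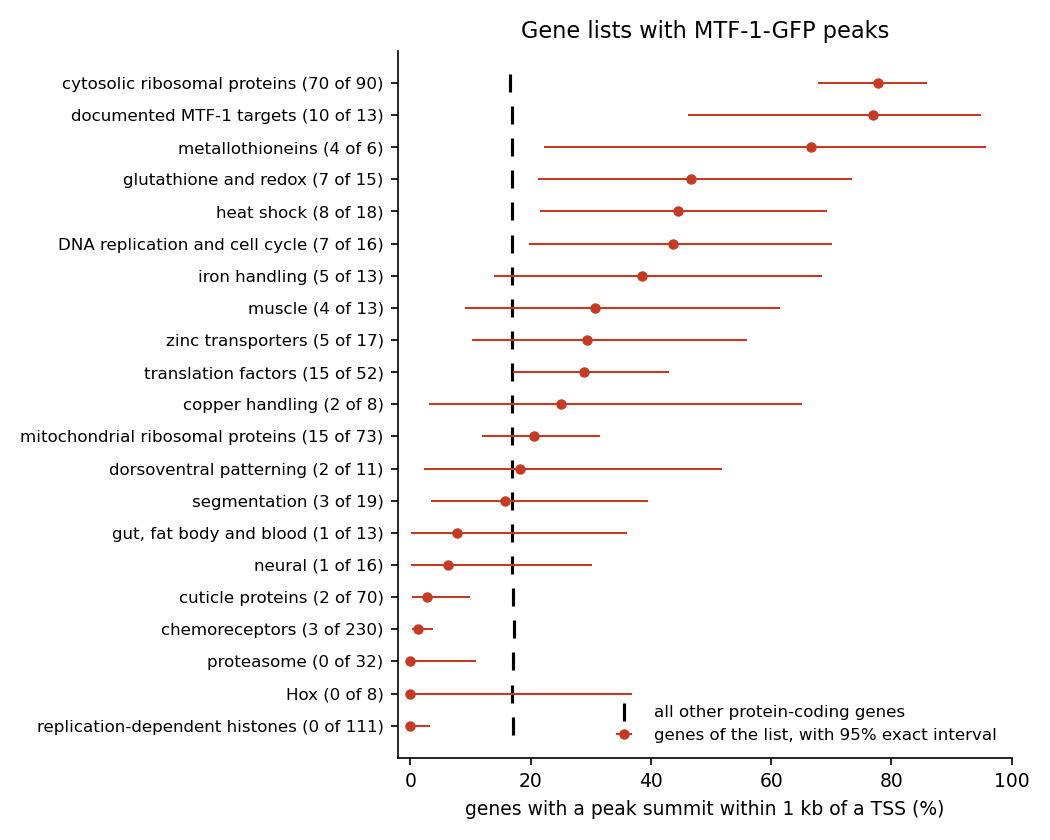
Share of the genes of each list with a peak summit within 1 kb of a TSS (red points with 95% exact intervals, counts beside the names) and of all other protein-coding genes (black bars), in percent. Cytosolic ribosomal protein genes (77.8%) and documented targets (76.9%) lie highest.

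Peaks clustered at transcript starts. Of the 3587 summits, 2219 (61.9%; 60.2 to 63.5) lay within 1 kb of a TSS, against 30.6% of 14859 background regions (Fisher's exact p = 3.94e-257), and the median distance was 480 bp against 2318 bp. The strongest regions of each replicate alone gave 62.5% (replicate 2) and 59.2% (replicate 4). Promoters held 50.5% of summits against 19.0% of the background. Introns held 34.3% against 44.6%, intergenic sequence 11.8% against 23.3%, coding exons 0.390% against 8.79% and 3′ UTRs 1.06% against 2.29%, and these 5 differences passed (largest BH-adjusted Fisher's exact p = 1.01e-06). The coding exon share was 1.14% in replicate 2 alone and 0.279% in replicate 4 alone. Shares in 5′ UTRs (1.00% against 0.983%) and other exons (0.976% against 1.00%) did not. The X chromosome carried 15.6% of the peaks on the X and large autosomes (558 of 3579), against 15.2% of background regions (Fisher's exact p = 0.605). Against random positions, 18.0% of which fell on X, the X share was lower (Fisher's exact p = 0.000224), with 23.7 peaks per Mb on X and 27.7 on the autosomes. Chromosome 4 had 8 peaks (5.93 per Mb).

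The MRE core was then sought at the summits. It occurred within 50 bp in 410 peaks (11.4%; 10.4 to 12.5) and in 8.28% of their flanks, an excess of 3.15 percentage points (1.76 to 4.54; exact McNemar p = 8.93e-06). The size of the excess depends on the side drawn for each flank. Over 1000 other draws it ran from 1.87 to 3.82 points with a median of 2.79, and the exact McNemar p was at most 0.0114. Background regions had it in 8.64% (Fisher's exact p = 4.09e-07). Of the 8 forms of the core, 2 passed. TGCACAC was present at 3.51% of summits and 1.95% of flanks (exact BH-adjusted p = 0.000516), and TGCGCAC at 1.81% and 0.836% (adjusted p = 0.00170); they passed in 1000 and 936 of the other draws. The other 6 forms did not pass, with exact adjusted p from 0.561 to 1. Among the 50 strongest peaks, 26% had a core (13; 14.6 to 40.3) against 12% of flanks (exact McNemar p = 0.167, under 0.05 in 375 of the 1000 other draws), and 20% had TGCACAC against 0% of flanks (0% to 2% over the draws). The excess was not the same in the replicates. The strongest regions of replicate 2 had a core in 13.2% against 8.11% of flanks (exact McNemar p = 6.01e-12), and those of replicate 4 in 9.03% against 7.78% (p = 0.0612), so the call was lost without replicate 2. Over the other draws the median flank share was 8.42% in replicate 2 and 8.53% in replicate 4, and the call was made in 1000 and 3 of them; the difference between the replicates was not tested. Summit windows also differed in base composition, with a mean GC content of 43.7% in replicate 2 and 36.9% in replicate 4, where their flanks had 41.3% and 42.3%. Over all thresholded peaks, signal did not differ detectably with a core (median 151) and without (median 154; difference -0.03 on the log2 scale, two-sided permutation p = 0.518).

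**Figure D4:**
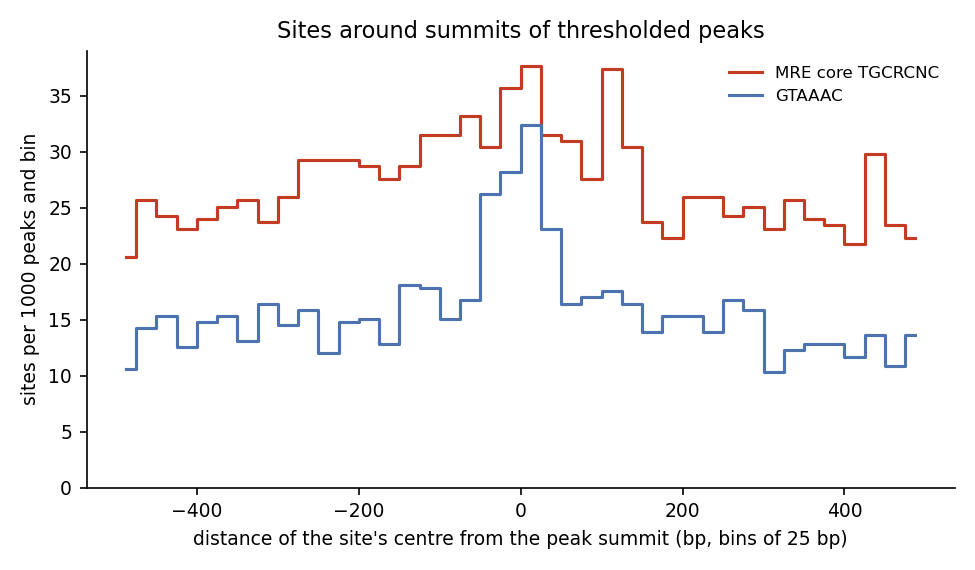
Number of MRE cores (red) and of the 6-mer GTAAAC (blue) per 1000 thresholded peaks in bins of 25 bp, against the distance of the site's centre from the summit in bp. GTAAAC reaches 32.3 per 1000 peaks in the bin just right of the summit, and MRE cores reach 37.6 there and 37.4 at 100 to 125 bp to the right, over a higher surround.

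Of the 17 other motifs, 7 were more frequent at summits than at flanks. These included the MRE forms TGCACNC (6.41% against 4.74%) and TGCGCNC (5.35% against 3.74%), each of which lost its call in replicate 4 alone and in the stricter set. Over the 1000 other draws of the flank side, 4 to 11 of the motifs passed as higher. DRE and the M1BP site passed in all of them, Su(Hw) in 996, TATAAA in 989, TGCGCNC in 958, CTCF in 902 and TGCACNC in 673. The promoter elements DRE (TATCGATA; 1.56% against 0.446%, exact BH-adjusted p = 2.04e-05) and the M1BP site (GGTCACAC; 1.37% against 0.223%, adjusted p = 3.96e-08) had the largest ratios. Summits and flanks were not matched on distance to a TSS, and 50.5% of summits lay in promoters. For these elements and TATAAA, the difference was therefore not separated from position relative to a TSS. The insulator motifs of Su(Hw) (5.05% against 3.18%, exact adjusted p = 0.000549) and CTCF (0.781% against 0.251%, adjusted p = 0.00622) passed as well, though CTCF did not in replicate 4 alone (adjusted p = 0.555). TATAAA passed (3.12 percentage points above the 11.9% of flanks, exact adjusted p = 0.000574), but in replicate 2 alone it was rarer at summits (10.6% against 13.0%, adjusted p = 0.00352). The remaining 10 motifs did not pass, among them the GAGA site (3.35% against 2.51%, exact adjusted p = 0.0813), Zelda, AP-1, the heat shock element and the homeodomain core. In replicate 2 alone, the GAGA site (5.27% against 2.59%), the E-box CAGCTG (6.72% against 4.71%), the initiator (11.7% against 9.84%) and the CA repeat (4.46% against 3.40%) passed as higher at summits and the homeodomain core as lower (4.21% against 6.80%), and in replicate 4 alone the GATA site passed as higher (22.7% against 17.4%). With 100 bp on each side of the summit, the GAGA site, CAGCTG and the GATA site passed (exact adjusted p = 0.000123, 0.00132 and 0.00616), and with 25 bp DRE, CTCF and TATAAA did not pass (exact adjusted p from 0.0905 to 0.113). At 50 bp and against background regions in place of flanks, the GAGA site (3.35% against 1.84%), the GATA site (20.1% against 16.3%) and CAGCTG (6.13% against 5.16%) were higher. Their BH-adjusted two-sided Fisher's exact p were 5.01e-07, 4.47e-07 and 0.0350. The others of the 10 did not pass there.

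Without an assumed motif, 151 of 2080 6-mers were more frequent at summits and 217 less frequent (exact McNemar tests, BH-adjusted p under 0.05); in replicate 4 alone the numbers were 287 and 560, and over other draws of the flank side they ran from 126 to 190 and from 179 to 272. The 6-mers higher at summits held 2.11 G or C letters on average, and the lower ones 3.58. Summit windows had a mean GC content of 40.2% and flanks 42.1%, so these counts do not separate specific sequences from base composition. The clearest loss was CCAGGA, in 0.418% of summits and 3.29% of flanks (exact adjusted p = 4.24e-18). The gain of smallest adjusted p was GTAAAC, in 9.81% of summits and 4.24% of flanks (exact adjusted p = 2.10e-17), and it passed in replicate 2 (8.87% against 4.99%) and in replicate 4 (9.34% against 4.66%). TAAACA, which overlaps it, was found in 17.2% and 10.7% (exact adjusted p = 4.29e-13). Together they spell GTAAACA, the leading 7-mer (6.77% against 2.26%, exact adjusted p = 1.50e-16), which holds the core bound by forkhead proteins. AAATAT (25.6% against 17.0%) and TAAATA (24.2% against 16.3%) had smaller adjusted p than TAAACA over all peaks, and over the other draws their median exact adjusted p (1.08e-15 and 5.14e-16) was also below that of GTAAAC (5.86e-15), but in replicate 2 alone they did not pass (exact adjusted p = 0.325 and 0.0881), and AAATAT reached 30.8% against 16.3% in replicate 4, whose summits were the richer in A and T. Of the 6-mers inside the MRE, TGCACA passed (9.53% against 6.94%, exact adjusted p = 0.00130), as did GCGCAC (5.41% against 3.96%, adjusted p = 0.0295), while GCACAC and TGCGCA did not (adjusted p = 0.0571 and 0.194). These calls depend on the draw, as GCGCAC passed in 761 and GCACAC in 910 of the 1000 other draws.

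The replicates were compared by the overlap of their strongest regions. Of the 3587 strongest regions of replicate 2, 2267 (63.2%; 61.6 to 64.8) overlapped 1 of replicate 4, and 60.4% did in the other direction. Random draws from the same lists gave 7.43% on average and 9.09% at most (one-sided permutation p = 0.0001, the smallest possible). Over 13998 regions listed in both, signal correlated with Spearman's rho of 0.56 and Pearson's r of 0.70 on the log2 scale (two-sided permutation p = 1e-05 for both, the smallest possible). This correlation is across regions, which are not independent replicates. It was 0.47 (rho) over the 3630 shared regions at thresholded peaks and 0.26 over the 10368 others. Of the thresholded peaks, 96.0% were overlapped by a region of the replicate 2 list and 99.3% by one of replicate 4. The thresholded list was derived from these same lists. The split of the correlation by thresholded peaks and these overlaps are therefore no independent measure of agreement.

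**Figure D5:**
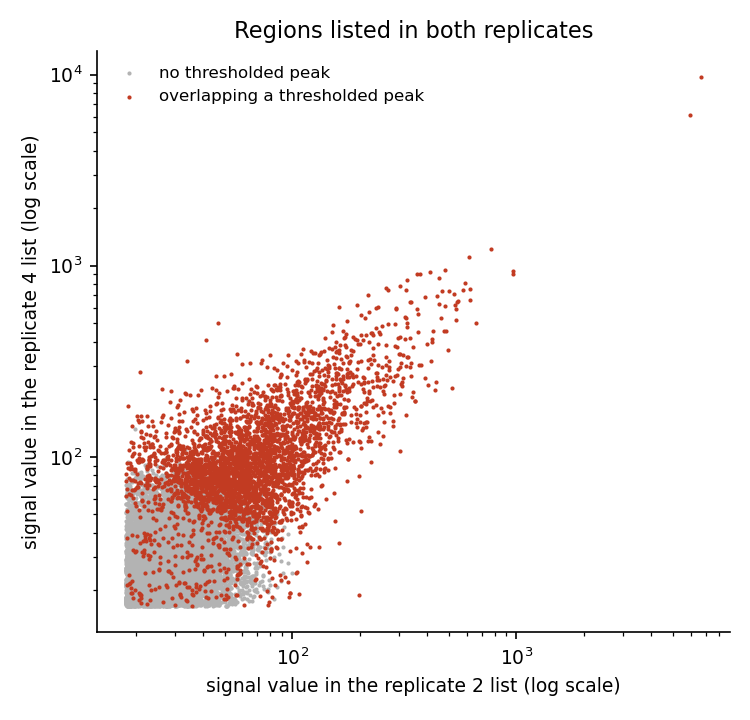
The authors' signal value in the replicate 2 list against that in the replicate 4 list (both log scale) for the 13998 regions listed in both, with those at a thresholded peak in red. The MtnA and ferritin regions lie at the upper right, at 6674 and 5948 in replicate 2.

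The neighbourhood of the MTF-1 gene (3L 9430312 to 9439490) was examined because the line expresses a tagged form of it. Within 20 kb, 9 of 27 candidate regions were thresholded peaks (33.3%), percentile 91.5 among 10000 windows around other genes. Background regions there had a median signal of 31.6, against 33.7 elsewhere, at percentile 17.3. The background median there rested on 5 regions. With 10 kb on each side, 8 of 17 candidate regions were thresholded peaks (percentile 95.2), and 1 background region lay at percentile 8.05. With 50 kb on each side, 17 of 46 candidate regions were thresholded peaks, at percentile 99.0, and the background signal was at percentile 70.1.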

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

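Other draws of the flank side, the counting of peaks only for the nearest TSS and the removal of genes near MTF-1 were chosen after the data were seen. The share of peaks near TSSs, the 5 annotation classes that passed and the count of documented targets (8 to 11 of 13) kept their direction and side of the threshold under every alternative run; shares in 5′ UTRs and other exons changed direction without passing. Replicate overlap under the alternatives had no p-value but lay above the highest chance draw. The number of gene lists that passed was 6 to 9. The MRE share ranged from 9.03% to 13.2% when 1 replicate was left out, and its call was lost without replicate 2; the cause was not tested. It passed in the stricter set with the flanks drawn (exact McNemar p = 0.0182), but in only 340 of 1000 other draws there. The X share of 15.6% was below that of random positions (18.0%), in place of slightly above the background; the cause was not tested. Of the other motifs, 4 passed with 25 bp on each side, a window in which fewer sites can be found. With 1 replicate left out, TATAAA ranged from 10.6% to 18.8% of summits and the CA repeat from 3.04% to 4.46%; without replicate 4, TATAAA turned lower than at flanks and the CA repeat higher, and the cause was not tested. The number of 6-mers higher at summits ranged from 207 to 287 when 1 replicate was left out, against 151, and that of lower ones from 183 to 560, against 217; the higher number was 60 with 25 bp and 257 with 100 bp on each side; the cause was not tested. Within 5000 bp, 14 proteasome genes had a peak, which turned that list from fewer to more than other genes without passing; the cause was not tested. Among the single motifs, annotation classes and gene lists, 160 of the values under other settings and 70 of those with a replicate left out kept their call, 17 and 8 lost it, and 7 and 8 gained one. A change of direction where neither value passed (34 cases) was counted as kept. Leaving out regions off the main chromosome arms removed none. Depth is unknown, so peaks missing at MtnB, MtnF or CG10505 may lie below what these libraries could detect.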

Other observations

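The tests of promoters by number of cores, tRNA genes, signal by number of cores, the growth of the MRE excess with the window and windows with a like number of transcript starts were devised after the peak lists had been seen, and the test of the core in peaks below rank 500 after its result was seen. The windows around the MTF-1 gene were set beforehand, but not the number of candidate regions as their measure. Protein-coding genes with more MRE cores within 300 bp of a TSS had a peak more often: 12.4% of 7940 genes with none, 20.1% of 4082 with 1, 26.4% of 1429 with 2 and 37.0% of 494 with 3 or more (95% exact interval 32.8 to 41.5). The core written backwards without complement, CNCRCGT, which is not itself an MRE, gave a like gradient: 14.02% of 10007 genes with none, 22.1% of 3108 with 1, 32.9% of 691 with 2 and 36.0% of 139 with 3 or more. Still, an MRE core TGCACAC followed by GT holds a match of it, as in the MtnA window. Such overlaps were not counted. Genes with several TSSs had more sequence searched; among genes with 1 TSS the MRE shares were 10.2% of 6557 with none and 23.1% of 229 with 3 or more. Genes for tRNAs, which RNA polymerase III transcribes, had a peak within 1 kb in 33 of 290 (11.4%).

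Most thresholded peaks carried no MRE core within 50 bp of the summit, and 3 explanations were weighed. If only the strongest peaks held sequence-specific binding, the 3087 peaks below rank 500 would show no excess. They had a core in 11.3% against 9.04% of flanks, an excess of 2.24 percentage points (95% interval 0.745 to 3.73, exact McNemar p = 0.00348). The lower bound lay above 0 in 999 of 1000 other draws of the flank side. These values show an excess of the core below rank 500 for the thresholded peaks as a set. The test was devised after its result was seen, so it cannot decide against that explanation. Replicate 4 alone gave no excess past the threshold over its strongest regions. The excess was uneven by rank. At ranks 51 to 500 and 501 to 1500 it was 1.11 and 1.5 points (exact McNemar p = 0.672 and 0.295). At ranks 1501 to 2500 and 2501 to 3587 it was 3.1 and 2.76 points (exact McNemar p = 0.0207 and 0.0421). The exact McNemar p was under 0.05 in 29, 42, 528 and 960 of 1000 other draws, in that order. Summits placed away from the bound site may account for part of the pattern: the excess grew 1.45 times (1.04 to 2.13) when 100 bp were searched on each side, and this interval leaves it open. Highly transcribed loci that give peaks without a bound site also remain open, since tRNA genes had a peak 0.956 times as often as protein-coding genes with 1 TSS (0.690 to 1.32; two-sided Fisher's exact p = 0.854), while cytosolic ribosomal protein genes, also highly transcribed, stood highest among the lists. The design has no group without the tag or with another metal supply, so no explanation by condition was tested.

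A thresholded peak without a core lay at the MTF-1 TSS, and the labels do not say whether the tagged gene is an added copy. Reads of an added copy could raise its whole neighbourhood: 27 candidate regions lay within 20 kb, against a median of 13 around other genes, at percentile 96.4, with 95.8 for 10 kb and 91.3 for 50 kb on each side. The neighbourhood was also dense in transcript starts (27 against a median of 15); among 1582 windows with a like number of starts, the number of candidate regions was at percentile 95.6 (94.5 to 96.6) with 10 kb on each side at 96.3 and with 50 kb at 88.7, and because these values lie on both sides of the bounds set for it, that density cannot be told apart from an added copy as the reason. The low background signal given in the report is not what raised coverage would give, but background regions were chosen by low signal, which voids that comparison. No biological explanation was tested.

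The hypothesis that peaks with several MRE cores have the higher signal was tested within the thresholded list. The 21 peaks with 3 or more cores within 100 bp had a median signal of 219.9 and the 2837 with none 153.8, a difference of 0.52 on the log2 scale (two-sided permutation p = 0.00882), while peaks with 1 or 2 cores had medians of 152 and 143. Without peaks of the documented targets, 17 peaks with 3 or more cores remained with a difference of 0.44 (95% bootstrap interval -0.23 to 0.81; permutation p = 0.0282), which leaves open whether it rests on those genes. For promoters, the share of genes with a peak was 2.98 times as high with 3 or more cores as with none (2.62 to 3.39), but 2.57 times as high (2.04 to 3.22) for the backwards core. Among genes with 1 TSS the ratios were 2.27 (1.78 to 2.91) and 1.81 (1.07 to 3.09), so the number of TSSs does not account for the whole gradient. Base composition may, and the gradient cannot be ascribed to the MRE from these data. The backwards core cannot settle this, since its matches can overlap MRE cores.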
